A study of Homo sapiens with 6 samples.

How the data were processed

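RNA-seq libraries of 6 samples of H1299 cells were analysed: 3 with a guide RNA against SETDB1 and 3 with a control guide. Groups and replicate numbers were taken from the sample titles, and each group was made with 1 guide. Per the labels' protocols, total RNA of frozen cells was used for libraries with an Illumina TruSeq RNA kit, and whether the kit kept the strand is not given in the sources used here. The authors deposited 1 table of raw read counts per gene with Ensembl identifiers. The submitters' processing notes name FastQC, TopHat2, HTSeq and the GRCh38.p7 genome build without versions, and the settings of the aligner and counter are not given in the sources used here. The deposited counts were whole numbers, and every row had at least 1 library with more than 10 counts (smallest row maximum 11), so genes under that level were not analysed here.

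The table had 18677 rows. Identifiers were matched without their version to GENCODE 29 (GRCh38), which named 18595 of them; 16484 had the same version. Coordinates are those of GENCODE 29. For 19 pseudoautosomal genes the table held a row for each of the X and Y copies, with similar counts. Reads shared between near-identical genes (SPANX, histone, heat shock, zinc finger and protocadherin families) and reads in overlapping or antisense genes can have been split, dropped or counted in the wrong gene, so values of such genes are uncertain.

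Total counts per library ranged from 29532057 to 35941288, so that 1 count was 0.0282 to 0.0334 CPM. Replicates of a group differed by more than counting error, with chi-square per degree of freedom from 2.33 to 10.4, so no library was counted as a copy of another. Tests were run in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the group, which left 17675 and removed 1002. Libraries were scaled by TMM, with factors from 0.976 to 1.02, and tested with robust quasi-likelihood fits (glmQLFit and glmQLFTest) of SETDB1 knockout against control. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. CPM used the TMM-scaled totals. The common biological coefficient of variation was 4.89%.

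Where a group had 0 counts, the fold was computed against a floor of 3 counts over the group and given as a lower bound. Where a group had 1 to 3 counts, the ratio was given with its exact 95% counting interval. Floors and intervals cover counting error only.

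The 32 gene lists, the naming rule, the main tests and most of the alternatives were fixed before the data were examined. Lists were tested with limma 3.58.1 (camera, two-sided, preset correlation of 0.01), with Benjamini-Hochberg adjustment over the 32 lists. Camera with an estimated correlation and fry were alternatives. The naming rule took SETDB1, the 8 largest rises and 8 largest falls among called genes whose groups did not overlap and whose higher group had at least 1 CPM, the 4 smallest p-values in each direction, and up to 2 rising and 2 falling called members of each list. Clone-style names, LINC, LOC, MIR and SNOR names and pseudogenes named with a P were left out of the largest changes. Some genes that the rule takes are not reported here.

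The alternatives were DESeq2 size factors, library size alone and upper-quartile scaling; no filter and a filter of at least 1 CPM in 3 libraries; DESeq2 1.42.0 and limma-voom; an adjusted p under 0.01 and a test against a fold of 1.5 (glmTreat); the replicate number as a block; and each library left out in turn. After the data were examined, 2 more were added: the median log2 fold change of 25 expressed genes on each side of a gene (log2 CPM above 3) was taken out of the gene's values, and the rows of pseudoautosomal copies were added together.

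The steps were tested on simulated counts for SETDB1 knockout against control, drawn from the control group's means and the real library sizes with changed genes of known size. Among 17004 simulated genes tested, edgeR recovered 42.6% of the changes of 0.25 on the log2 scale, 74% of those of 0.5, 91.5% of those of 1 and 100% of those of 2. It called 10 of 16812 unchanged genes. In a further simulation with 16997 genes and 31 lists, camera called the list that had been raised and 0 others. A segment simulated at -0.5 had a neighbourhood median of -0.50. Genes were drawn independently in these simulations, so they do not show how camera behaves where genes move together. Only 47 to 50 tested genes were changed per size, whereas 63.5% of the genes were called in the real comparison. The adjustment depends on that share, so these rates do not give the sensitivity or error of the real comparison.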

Results

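H1299 is an established human non-small cell lung cancer line without functional p53. The study used 6 RNA-seq libraries from these cells: 3 from cells that carried a guide RNA against SETDB1, and 3 from cells that carried a control guide. Each group was made with 1 guide, and the labels do not say whether the replicates were separate cultures, so every p-value measures only the spread between these samples. The libraries held 29532057, 34320279 and 33582323 counts in the SETDB1 knockout and 30729681, 31816588 and 35941288 counts in the control knockout. Levels are in CPM (read counts scaled by the size of the library), given as mean ± SD over the 3 libraries of a group, and log2 fold changes are SETDB1 knockout over control with their standard error (SE).

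SETDB1 (ENSG00000143379, GRCh38 chromosome 1, 150926263 to 150964744) encodes a histone methyltransferase that deposits the repressive H3K9me3 mark and works with the co-repressor TRIM28. Its mRNA stood at 40.59, 36.06 and 39.12 CPM in the SETDB1-knockout libraries and at 45.01, 43.96 and 41.57 CPM in the control libraries. The group levels were 38.6 ± 2.31 and 43.5 ± 1.76 CPM, a log2 fold change of -0.17 ± 0.06 (SE; adjusted p = 0.0151, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). The call was lost without SETDB1-knockout replicate 2, at a log2 fold change of -0.13 (edgeR adjusted p = 0.0896, in a range of 4.84e-04 to 0.0896 over the alternatives). It was also lost with library size alone, at -0.13 (edgeR adjusted p = 0.0605). The genes around SETDB1 had a median of 0.11, and with the neighbourhood median taken out its log2 fold change was -0.28 (edgeR adjusted p = 4.84e-04). A frameshifting edit need not lower the mRNA, so this level checks the sample labels only in part.

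The comparison asks which transcripts differ when SETDB1 is targeted. Genes that were silent or nearly silent in the control cells were expressed in the SETDB1-knockout cells, among them CTCFL, SPANXB1 and PIWIL1, which are known from the germline, the neural genes NCAM2 and SLITRK6, and the imprinted growth factor gene IGF2. TNC, FSTL1 and MAP1B, which encode a matrix protein, a secreted glycoprotein and a microtubule-associated protein, fell. Of 23 genes of cholesterol synthesis 20 fell, while 23 of 34 replication-dependent histone genes and 26 of 41 clustered protocadherins rose. These list calls were made by camera with a preset correlation and were lost with an estimated correlation (adjusted p = 0.390, 0.253 and 0.610 with an estimated correlation). The interferon response list as a whole did not pass its test, although its member BST2 went from nearly no reads to 22.7 ± 0.638 CPM.

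Of 17675 genes tested, 5635 were higher and 5584 lower in the SETDB1 knockout by edgeR's quasi-likelihood test, together 63.5% of the genes tested. Most of these changes were small, since 57.0% of the called genes differed by less than 1.5-fold. Changes of at least 2-fold were called for 1262 higher and 1021 lower genes, and changes of at least 10-fold for 253 higher and 25 lower genes. The libraries of both groups did not overlap in CPM for 66.8% of the genes tested, against the 10% that chance gives for 3 against 3. The first principal component held 89.1% of the variance and separated the groups.

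By fitted fold, the 8 largest increases taken by the naming rule were of genes with 0 counts in all 3 control libraries. Fitted folds over 0 counts are not exact, so genes with 1 to 3 control counts can have risen as much. LRRC38, an auxiliary subunit gene of potassium channels (chromosome 1, 13474977 to 13514048), reached 59.5 ± 2.79 CPM and was at least 1927-fold higher, taking 3 counts over the control group as the floor. Its neighbour PDPN (chromosome 1, 13583465 to 13617957), which encodes the membrane glycoprotein podoplanin, reached 21.9 ± 0.726 CPM and was at least 708-fold higher. The matricellular protein gene SMOC2 rose to 24.7 ± 1.18 CPM, and the dipeptidyl peptidase-like gene DPP6 rose to 18.2 ± 0.863 CPM. The neural genes SLITRK6 and NCAM2 rose to 10.8 ± 0.774 and 7.57 ± 0.141 CPM. On the X chromosome, the cancer-testis gene SPANXB1 rose to 23.5 ± 1.48 CPM and LDOC1 to 7.18 ± 1.04 CPM, and reads of SPANXB1 can be shared with its near-identical paralogs. All 8 of these genes had an edgeR adjusted p of 2.20e-13 or lower.

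Among the genes with the smallest p-values, DHRS2, a short-chain dehydrogenase gene, rose 117-fold from 1.97 ± 0.438 to 229 ± 9.99 CPM. CTCFL, the germline paralog of the insulator protein CTCF, rose from 0.2181 ± 0.1197 to 132 ± 8.76 CPM; the genes around it had a median log2 fold change of 0.45. The neurofilament gene NEFH rose 20.3-fold to 133 ± 4.09 CPM. ESRG, a non-coding RNA of embryonic stem cells that derives from an endogenous retrovirus, rose 77.8-fold to 62.8 ± 2.25 CPM. The edgeR adjusted p was 2.41e-20 or lower for each of these 4.

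**Figure D1:**
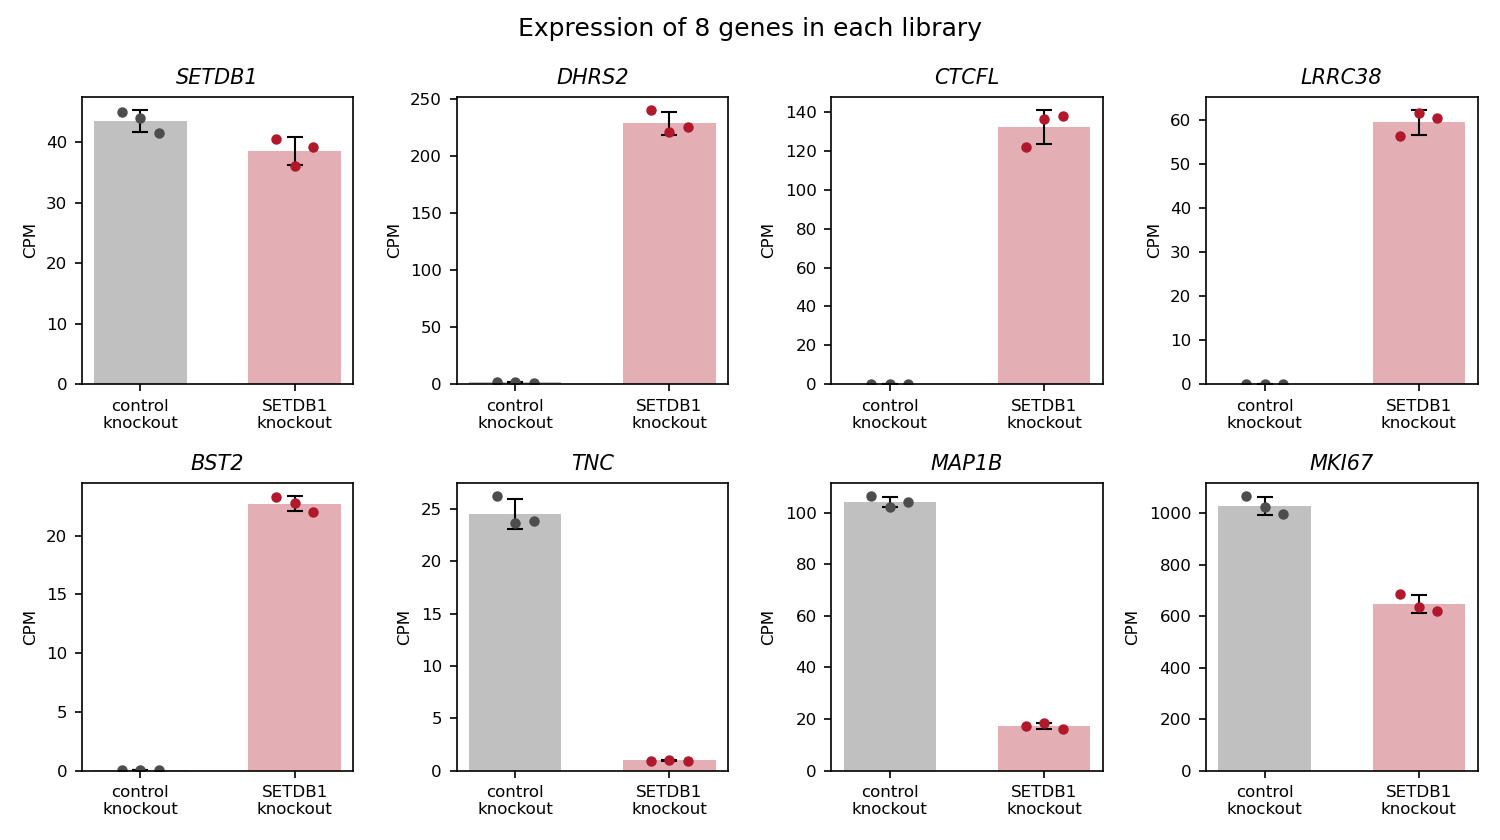
CPM (vertical axis, linear from 0) of 8 genes in each of the 6 libraries, with grey for the control knockout and red for the SETDB1 knockout. Points are libraries, bars are group means and error bars are the SD over 3 libraries; LRRC38 lies at 0 in all control libraries and at 59.5 CPM on average in the SETDB1 knockout, while SETDB1 itself differs little, at 38.6 against 43.5 CPM.

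Of the 8 steepest decreases taken by the naming rule, 6 were of genes under 10 CPM in both groups. The semaphorin receptor gene PLXNA2 had 2 counts in the SETDB1-knockout group against 103 in the control group, a ratio of 52.4 in favour of the control (95% counting interval 14.1 to 439). OLIG2 and PROX1, which encode developmental transcription factors, fell by 4.84 ± 0.30 and 4.68 ± 0.45 (SE) on the log2 scale. The neurotransmitter receptor genes GABRA5 and GABBR2 fell by 4.42 ± 0.30 and 4.37 ± 0.16; their neighbouring genes had medians of -0.41 and -0.43. SCUBE3, which encodes a secreted glycoprotein, fell by 3.96 ± 0.38. The edgeR adjusted p for these 6 genes was 2.46e-08 or lower.

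The other 2 were more abundant. TNC, which encodes the matrix protein tenascin C, fell by 4.65 ± 0.11 (SE) on the log2 scale, from 24.6 ± 1.42 to 0.970 ± 0.0608 CPM. ANKRD1, a mechanically responsive gene, fell by 3.97 ± 0.09 on the log2 scale, from 28.7 ± 1.13 to 1.83 ± 0.242 CPM, in a stretch of chromosome 10 where neighbouring genes had a median log2 fold change of -0.69. MAP1B, a microtubule-associated protein gene, fell 6.06-fold from 104 ± 1.97 to 17.2 ± 1.17 CPM. FSTL1, which encodes a secreted glycoprotein, fell 5.37-fold from 208 ± 15.8 to 38.8 ± 3.53 CPM. Each had an edgeR adjusted p of 2.40e-16 or lower.

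Gene lists fixed before the data were examined were tested with camera at a preset correlation, and 10 of 32 passed at an adjusted p under 0.05, with 5 up and 5 down. With an estimated correlation, camera called 0 of the 32 lists, with 1 at an unadjusted p under 0.05, while fry, which asks whether the members of a list move one way on balance, called 27. The list counts below are of members past the edgeR threshold over all genes, followed by the counts adjusted over the list alone.

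**Figure D2:**
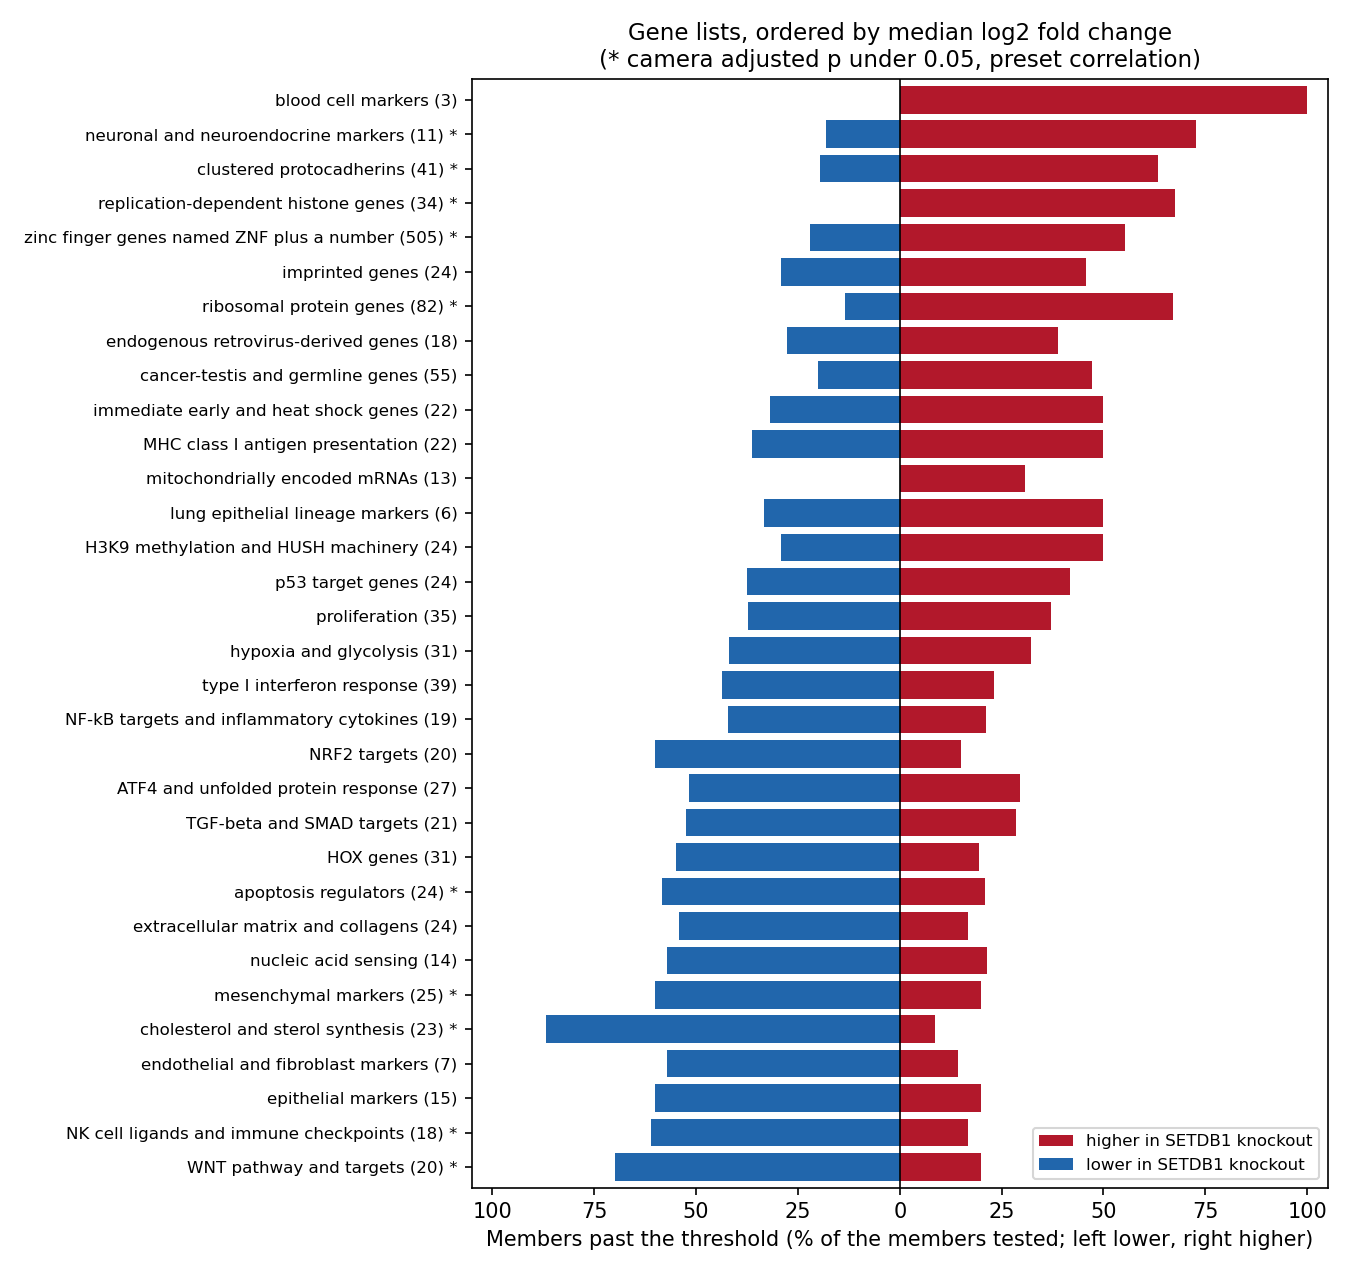
Share of each list's tested members (horizontal axis, percent; number of members in brackets) that were higher (red, right) or lower (blue, left) in the SETDB1 knockout, for all 32 lists ordered by median log2 fold change. Asterisks mark the 10 lists called by camera with the preset correlation; cholesterol and sterol synthesis has 20 of 23 members lower, and the replication-dependent histone genes have 23 of 34 higher and 0 lower.

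Zinc finger genes, many of which encode KRAB repressors that recruit TRIM28 and SETDB1 to chromatin, included 279 that rose and 111 that fell among 505 tested (285 and 113 adjusted over the list alone). Their median log2 fold change was 0.27 (camera adjusted p = 2.94e-04, and adjusted p = 0.390 with an estimated correlation). ZNF733P and ZNF479 on chromosome 7 had 0 counts in the control libraries and 5.68 ± 0.132 and 4.88 ± 0.333 CPM in the SETDB1 knockout, whereas ZNF853 and ZNF503 fell by 3.24 ± 0.36 and 2.55 ± 0.22 on the log2 scale. The median of the genes around the list's members was 0.15, and the call was lost when each gene's neighbourhood median was taken out (camera adjusted p = 0.136). Other zinc finger genes were among these neighbours, so this step can also take out a rise of the list itself. Reads of related zinc finger genes can be shared.

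Clustered protocadherins, adhesion molecules encoded in tandem arrays on chromosome 5, rose in 26 and fell in 8 of 41 members (26 and 8 adjusted over the list alone), with a median log2 fold change of 0.78 (camera adjusted p = 0.00477, and adjusted p = 0.610 with an estimated correlation). PCDHB8 rose 4.60-fold to 2.15 ± 0.183 CPM and PCDHB16 rose 3.08-fold, whereas PCDHB12 and PCDHGA10 fell by 0.84 ± 0.25 and 0.79 ± 0.17 on the log2 scale. These genes overlap or resemble each other, so their separate values are uncertain. Cancer-testis and germline genes rose in 26 and fell in 11 of 55 members (26 and 11 adjusted over the list alone), with a median of 0.17, and the list missed the threshold (camera adjusted p = 0.0537, and adjusted p = 0.610 with an estimated correlation). It passed with the neighbourhood median taken out (camera adjusted p = 0.0129), with library size alone (0.0491), without SETDB1-knockout replicate 1 (0.0498) and without control replicate 3 (0.0191). PIWIL1, a germline piRNA pathway gene, rose from 1 to 218 counts per group, a ratio of 214 (95% counting interval 38.1 to 8500), while TDRD12 and MAGEA3 were already high in control cells and fell, by 0.79 ± 0.05 and 0.43 ± 0.05 on the log2 scale; the neighbours of TDRD12 had a median of -0.71, and with the neighbourhood median taken out it lost its call at -0.0796.

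The list named for endogenous retrovirus-derived genes, whose rule also took PEG10 and RTL genes but not ESRG, was mixed. Of its 18 members 7 were higher and 5 lower (7 and 5 adjusted over the list alone, camera adjusted p = 0.389). The deposited counts are per gene, so retroviral copies outside annotated genes were not measured. ERVH-1 had 314 counts in the SETDB1 knockout and 2 in the control, a ratio of 154 (95% counting interval 42.4 to 1280), and HHLA1 rose 45.5-fold to 25.01 ± 1.73 CPM, whereas RTL5 fell by 1.47 ± 0.10 and ERVMER34-1 by 0.98 ± 0.14 on the log2 scale. Of 24 imprinted genes, 11 rose and 7 fell (11 and 7 adjusted over the list alone; camera adjusted p = 0.187). IGF2 rose 158-fold to 10.3 ± 0.673 CPM and GRB10 went from 0 counts to 1.12 ± 0.129 CPM, while PLAGL1 and MEST fell by 1.47 ± 0.07 and 1.33 ± 0.12. In the list of H3K9 methylation and HUSH machinery, 12 rose and 7 fell of 24 (12 and 7 adjusted over the list alone; camera adjusted p = 0.444). EHMT2, another H3K9 methyltransferase gene, rose 1.98-fold, and ATF7IP, which encodes a SETDB1 cofactor, rose 1.88-fold to 226 ± 7 CPM.

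The type I interferon response list had 9 members higher and 17 lower of 39 (9 and 17 adjusted over the list alone), a median log2 fold change of -0.10 and no call (camera adjusted p = 0.177); fry gave the opposite direction. BST2, which encodes the antiviral membrane protein tetherin, had 3 counts in the control group and 2240 in the SETDB1 knockout, a ratio of 734 (95% counting interval 251 to 3561). IFITM2 rose 2.33-fold, whereas IFIT3 and SAMD9 fell by 1.80 ± 0.13 and 1.38 ± 0.08 on the log2 scale, and the neighbours of IFIT3 had a median of -0.69. Nucleic acid sensors were lower in 8 and higher in 3 of 14 (8 and 3 adjusted over the list alone; camera adjusted p = 0.141); TMEM173, which encodes STING, fell by 1.42 ± 0.09, and IRF3 rose 2.12-fold in a stretch with a neighbour median of 0.69.

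MHC class I antigen presentation genes were higher in 11 and lower in 8 of 22 (11 and 8 adjusted over the list alone; camera adjusted p = 0.885), with a median of 0.14 and a mean of -0.03. The immunoproteasome gene PSMB9 and the transporter gene TAP1, which overlap on chromosome 6, rose 2.74-fold and 1.75-fold. PSMB8, another immunoproteasome gene beside them, fell from 21.7 ± 0.650 to 10.9 ± 0.468 CPM. NLRC5, a transactivator of MHC class I genes, fell by 2.003 ± 0.18 on the log2 scale. NF-kB targets and cytokines rose in 4 and fell in 8 of 19 (4 and 8 adjusted over the list alone; camera adjusted p = 0.330), with ICAM1 1.68-fold higher and TNFRSF9 8.37-fold lower. Ligands of NK cells and immune checkpoint genes fell in 11 and rose in 3 of 18 (11 and 3 adjusted over the list alone), with a median of -0.65 (camera adjusted p = 0.0380, and adjusted p = 0.610 with an estimated correlation). The death receptor gene FAS fell from 43.7 ± 2.93 to 16.7 ± 0.248 CPM, with neighbours at a median of -0.68, and the NKG2D ligand gene ULBP1 fell by 1.31 ± 0.08 on the log2 scale.

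More members fell than rose among both mesenchymal and epithelial markers. Mesenchymal markers fell in 15 and rose in 5 of 25 (15 and 7 adjusted over the list alone), with a median of -0.35 (camera adjusted p = 0.0380, and adjusted p = 0.390 with an estimated correlation), and the call was lost with the neighbourhood median taken out (camera adjusted p = 0.0626). TNC was among those that fell, while the gelatinase gene MMP2 rose 4.17-fold and TWIST2 rose 2.24-fold. Epithelial markers fell in 9 and rose in 3 of 15 (9 and 3 adjusted over the list alone; camera adjusted p = 0.0537), with the desmosome gene DSP 3.34-fold and the keratin gene KRT8 2.33-fold lower. This list passed with the neighbourhood median taken out (camera adjusted p = 0.0215), with library size alone (0.0364) and without SETDB1-knockout replicate 1 (0.0464), and had an adjusted p = 0.390 with an estimated correlation. Matrix and collagen genes fell in 13 and rose in 4 of 24 (13 and 4 adjusted over the list alone; camera adjusted p = 0.0574, and 0.0491 with library size alone), with FBLN2 3.24-fold higher and FBLN5 2.84-fold lower. TGF-beta and SMAD targets rose in 6 and fell in 11 of 21 (7 and 11 adjusted over the list alone; camera adjusted p = 0.356, with fry in the opposite direction). Its members moved strongly both ways, with ID2 7.29-fold and PMEPA1 3.83-fold higher and BAMBI 9.70-fold lower.

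WNT pathway genes and targets fell in 14 and rose in 4 of 20 (14 and 4 adjusted over the list alone), with a median of -0.70 (camera adjusted p = 0.0175, and adjusted p = 0.390 with an estimated correlation). The transcription factor genes LEF1 and TCF7L1 fell by 2.06 ± 0.09 and 1.49 ± 0.13 on the log2 scale. The members that rose included DKK1 and ZNRF3, which encode antagonists of the pathway and rose 1.81-fold and 1.49-fold; the neighbours of DKK1 had a median of -0.53. HOX genes fell in 17 and rose in 6 of 31 (18 and 6 adjusted over the list alone; camera adjusted p = 0.0574, and 0.0491 with library size alone), with HOXA13 6.995-fold and HOXB13 4.83-fold lower, and HOXA10 2.61-fold higher.

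Neuronal and neuroendocrine markers rose in 8 and fell in 2 of 11 (8 and 2 adjusted over the list alone), with a median of 0.87 (camera adjusted p = 0.0450, and adjusted p = 0.390 with an estimated correlation). MAP2 rose 5.44-fold and the synaptic vesicle gene SYP rose 3.52-fold, while ENO2 and UCHL1, which were already abundant, fell by 0.65 ± 0.06 and 0.54 ± 0.05. This call was lost when any 1 of the 6 libraries was left out, with camera adjusted p from 0.0533 without control replicate 3 to 0.215 without SETDB1-knockout replicate 1, and also with the neighbourhood median taken out (camera adjusted p = 0.0768). Of the lung epithelial lineage markers, 3 rose and 2 fell of 6 (3 and 2 adjusted over the list alone; camera adjusted p = 0.782). Their median log2 fold change was 0.07 and their mean 1.24. At least 2-fold rises were called for 2 members, and 1 member had 0 counts in all control libraries. Their summed level was 11.95 CPM in the SETDB1 knockout and 11.05 CPM in the control. AGER was 1.28-fold higher, a call lost with the neighbourhood median taken out (log2 fold change 0.13).

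Genes of cholesterol and sterol synthesis fell in 20 and rose in 2 of 23 (20 and 2 adjusted over the list alone), with a median of -0.59 (camera adjusted p = 4.54e-05, and adjusted p = 0.390 with an estimated correlation). HMGCS1, which encodes the enzyme upstream of HMG-CoA reductase, fell from 235 ± 14.1 to 97.7 ± 1.25 CPM, and MSMO1, a sterol demethylation gene, fell from 137 ± 7.23 to 52.5 ± 0.218 CPM. PMVK and TM7SF2 rose 1.31-fold and 1.23-fold, and TM7SF2 lost its call with the neighbourhood median taken out (log2 fold change 0.14). Replication-dependent histone genes rose in 23 of 34, with 0 lower (23 and 0 adjusted over the list alone), and had a median of 0.67 (camera adjusted p = 2.94e-04, and adjusted p = 0.253 with an estimated correlation). Their summed level over the 34 was only 102.8 CPM in the SETDB1 knockout and 75.65 CPM in the control. Whether capture of these mRNAs by the library kit differed between the groups was not tested. HIST4H4 and HIST3H2A rose 2.76-fold and 2.39-fold to 1.61 ± 0.167 and 3.96 ± 0.299 CPM; histone genes are near-identical copies, so their separate values are uncertain.

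Ribosomal protein genes rose in 55 and fell in 11 of 82 (56 and 11 adjusted over the list alone) by small amounts, with a median of 0.21 (camera adjusted p = 6.31e-04, and adjusted p = 0.694 with an estimated correlation). The list kept its call at the preset correlation with the neighbourhood median taken out (camera adjusted p = 8.92e-05). The genes around its members had a median of -0.01. Some members nevertheless lay where neighbouring genes had moved the same way. On chromosome 20, RPS21 rose 1.92-fold where neighbours had a median of 0.39. On chromosome 19, RPS16 and RPS19 fell 1.77-fold and 1.65-fold where neighbours had medians of -0.78 and -0.80, and with the neighbourhood median taken out neither was called, at log2 fold changes of -0.0477 and 0.0747. Mitochondrially encoded mRNAs rose in 4 of 13, with 0 lower (4 and 0 adjusted over the list alone; camera adjusted p = 0.187). Their share of all counts was 8.03, 7.43 and 7.33% in the SETDB1-knockout libraries and 7.33, 6.81 and 6.86% in the control libraries.

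Apoptosis regulators fell in 14 and rose in 5 of 24 (15 and 5 adjusted over the list alone), with a median of -0.30. The list passed (camera adjusted p = 0.0380), but not with the replicate number as a block (0.0509) or with an estimated correlation (0.390). Members with pro-apoptotic functions went both ways, with FAS and BMF lower and PMAIP1 and BAX 1.28-fold and 1.81-fold higher; neighbours of BAX had a median of 0.59. The p53 target list had 10 members higher and 9 lower of 24 (10 and 9 adjusted over the list alone; camera adjusted p = 0.885), with a median of 0.01 and a mean of -0.06; FDXR rose 2.14-fold. The proliferation list had 13 higher and 13 lower of 35 (14 and 13 adjusted over the list alone), with a median of 0.00 (camera adjusted p = 0.891). MKI67, a marker of cycling cells, fell from 1029 ± 34.7 to 648 ± 35.0 CPM and AURKB rose 1.62-fold, in stretches with neighbour medians of -0.45 and 0.56.

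Among metabolic and stress lists, hypoxia and glycolysis genes rose in 10 and fell in 13 of 31 (10 and 13 adjusted over the list alone; camera adjusted p = 0.874), with a median of -0.05 and a mean of 0.12. NDRG1 rose from 2 to 333 counts per group, a ratio of 164 (95% counting interval 44.9 to 1357). HK1 fell 2.31-fold and GPI 1.71-fold, with neighbour medians of -0.54 and -0.91, and with the neighbourhood median taken out GPI turned to a log2 fold change of 0.13. Genes of the ATF4 and unfolded protein responses rose in 8 and fell in 14 of 27 (8 and 14 adjusted over the list alone; camera adjusted p = 0.187), with the protein disulfide isomerase gene PDIA4 2.16-fold higher and VLDLR 2.66-fold lower. NRF2 targets rose in 3 and fell in 12 of 20 (3 and 12 adjusted over the list alone; camera adjusted p = 0.126), with AKR1B1 2.51-fold higher and ME1 3.22-fold lower. Immediate early and heat shock genes rose in 11 and fell in 7 of 22 (11 and 7 adjusted over the list alone; camera adjusted p = 0.330); the small heat shock protein gene HSPB1 rose 5.88-fold from 53.9 ± 1.74 to 317 ± 24.9 CPM, and ZFP36 fell 2.298-fold.

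Markers of other cell types stayed low in both groups. Of the blood cell markers, 3 were expressed highly enough to be tested and all 3 rose (3 adjusted over the list alone; camera adjusted p = 0.0603, and 0.0438 without control replicate 1), with ITGAM at 5.55 ± 0.548 against 2.73 ± 0.412 CPM. Their summed level was 6.71 CPM in the SETDB1 knockout and 3.03 CPM in the control. Of the endothelial and fibroblast markers, 1 rose and 4 fell of 7 (1 and 4 adjusted over the list alone; camera adjusted p = 0.126), with KDR at 1.65 ± 0.240 against 3.33 ± 0.293 CPM, and their summed level was 11.8 against 15.5 CPM.

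Expressed genes along several stretches of the genome shifted together. In 10 Mb windows with at least 20 expressed genes, 26 of 208 windows had a median log2 fold change of -0.4 or lower and 5 had a median of 0.4 or higher. On chromosome 10 from 50 to 140 Mb the median over 275 genes was -0.54 (95% interval -0.59 to -0.51), with 250 genes lower and 11 higher. In the first 10 Mb of chromosome 17 the median over 112 genes was 0.63 (95% interval 0.59 to 0.69). On chromosome 19 it was -0.87 over 44 genes from 30 to 36 Mb, -0.80 over 93 genes from 39 to 45 Mb and 0.71 over 179 genes from 47 Mb to the end. The bounds of these 5 stretches were chosen after the values were seen. Of 1371 genes in shifted windows 91.0% were called, against 67.8% of the genes in the other windows. The shifted windows were chosen on these same fold changes, so a higher share in them follows from that choice.

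**Figure D3:**
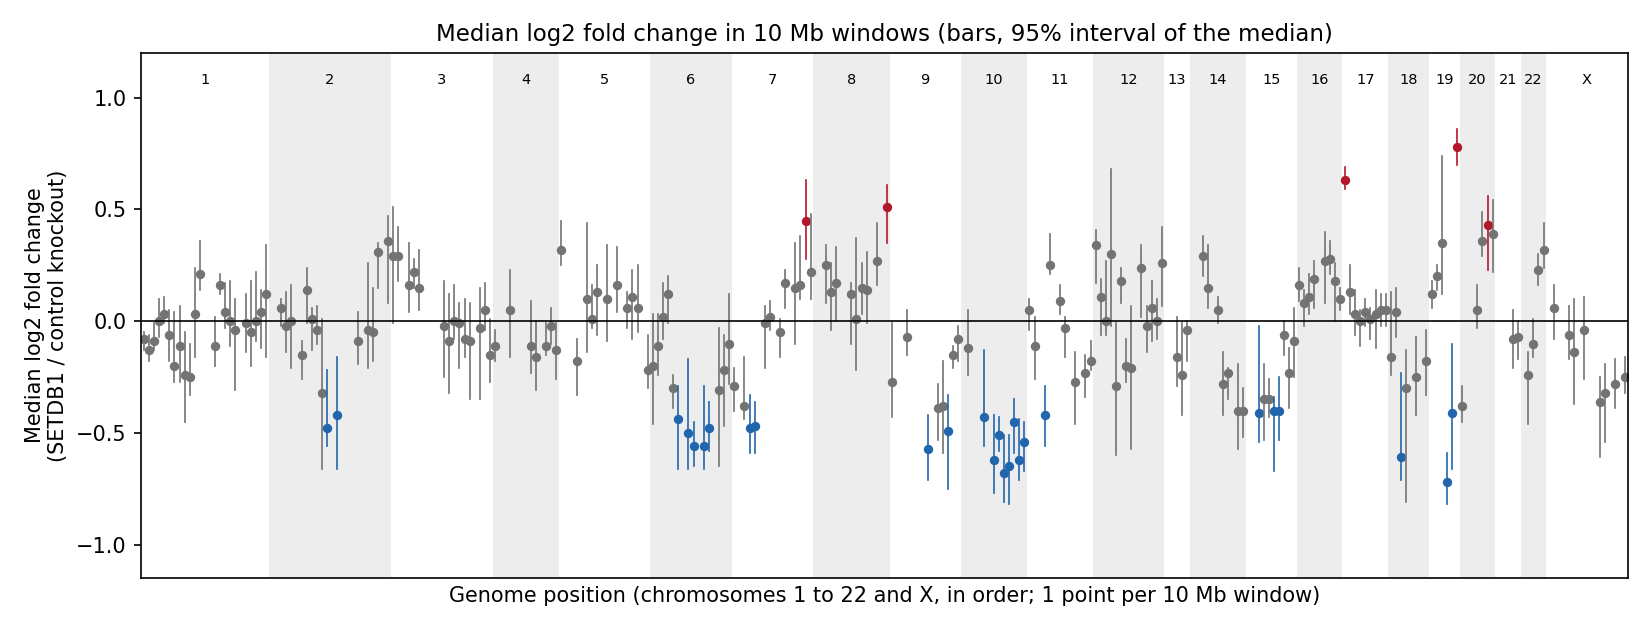
Median log2 fold change (vertical axis, SETDB1 knockout over control) of expressed genes in 208 windows of 10 Mb along chromosomes 1 to 22 and X (horizontal axis), with the 95% interval of each median. Blue marks the 26 windows at -0.4 or lower and red the 5 at 0.4 or higher; most windows of chromosome 10 past 40 Mb lie below -0.4 and the end of chromosome 19 lies at 0.78.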

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

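The removal of neighbourhood medians and the joining of pseudoautosomal copies were chosen after the data were examined. Higher and lower genes numbered 5072 to 6155 and 5088 to 5839 under the planned scalings, filters, tools, block and left-out libraries, and 4730 and 4724 at an adjusted p under 0.01. Against a fold of at least 1.5 they numbered 1556 and 1496, since small changes no longer count. With neighbourhood medians taken out they were 5345 and 4690, of which 8077 were called in the same direction as before, out of 11219. SETDB1 lost its call with library size alone (log2 fold change -0.13, edgeR adjusted p = 0.0605, in a range of 4.84e-04 to 0.0896) and ranged from -0.21 to -0.13 with 1 library left out. With neighbourhood medians taken out SETDB1 stood at -0.28. Among left-out libraries it lost its call only without SETDB1-knockout replicate 2; the cause was not tested. Camera called 0 lists with an estimated correlation and fry 27; fry turned the interferon list upward (adjusted p = 8.85e-04), and fry does not compare a list with other genes. The neuronal list was the only list call lost when a library was left out, and neighbourhood medians ended 3 list calls, left 7 and added 2, the cancer-testis and epithelial lists; library size alone added those and the matrix and HOX lists. Library size alone raised the share of calls that were higher from 50.2% to 54.7% and moved the median of all genes to 0.05. Of 1963 alternative values of the 131 genes other than SETDB1 taken by the naming rule, 1952 kept direction and call, 9 lost the call and 2 reversed: GPI at 0.13 and RPS19 at 0.0747, both with neighbourhood medians taken out. With the replicate number as a block, 5864 genes were higher and 5839 lower, and the calls of apoptosis regulators and neuronal markers were lost, both at a camera adjusted p of 0.0509. Whether the numbers pair the samples stayed unsettled. Deviations of same-numbered libraries correlated at 0.45, -0.15 and 0.27, and those of differently numbered libraries at -0.47 to 0.38. Depth limits genes near 0.03 CPM, the floor of 3 counts in a group.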

Other observations

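The tests of copy number, of regional shift in zinc finger genes, of GC content or length as the whole cause, of another cell line, of RNA from other cells, of copy gains around silent genes and of other splits were chosen after the results they bear on had been seen.

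Long non-coding RNAs were raised more often than they were lowered. Of 2260 tested, 319 (14.1%) were at least 2-fold higher and 103 (4.56%) at least 2-fold lower in the SETDB1 knockout, whereas of 13418 protein-coding genes 839 (6.25%) were higher and 857 (6.39%) lower. The odds that a gene changed at least 2-fold was higher were 3.16 times those of coding genes (Fisher's exact test, two-sided p = 7.03e-23) and 2.98 times when genes were compared within strata of abundance (Cochran-Mantel-Haenszel test, p = 8.06e-18); genes are not independent replicates. Of 1722 pseudogenes 79 were at least 2-fold higher and 49 lower.

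Strongly raised genes often lay beside each other. Of 475 genes raised at least 4-fold, 106 had a nearest non-overlapping gene that was also raised at least 4-fold, against a median of 12 and a highest value of 30 in 1000 shuffles among genes of like abundance. In 86 of the 106 the symbols of gene and neighbour differed in their first 3 letters, so paralogs alone did not make up the count. Clone-style names, such as AC099654.6 beside ZNF479, do not show a gene's family, so paralogs can remain among the 86. Of 190 genes lowered at least 4-fold, 5 had such a neighbour. Examples chosen after their values were seen are LRRC38 with PDPN on chromosome 1, PLA2G4A with ERVMER61-1 on chromosome 1, SPANXB1 with LDOC1 on the X chromosome, NDRG1 with ST3GAL1 on chromosome 8 and BST2 with its non-coding neighbour BISPR on chromosome 19. A hypothesis is that repression was lost over small domains that hold more than 1 gene. Read-through from 1 gene into the next was not tested, nor were other links between genes that lie very close. BST2, for example, ends at 17405648 and BISPR starts at 17405686.

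Expressed genes of whole chromosome stretches shifted together. GC content or gene length as the whole cause is argued against by 23 of 208 windows with a median of at least 0.4 after the trend was taken out, against 0 in the highest of 100 shuffles, although of the 31 windows past 0.4 before that, 21 kept it, fewer than the 80% set beforehand. A difference in DNA copy number between the knockout and control cells may underlie the shifts: of 30 windows chosen on every other gene, 100% kept their sign with a median of at least 0.2 in the genes left out. Any other influence on whole stretches would give this too, no DNA was measured, and an effect of SETDB1 loss on them stays open.

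Zinc finger genes rose as a list (camera adjusted p = 2.94e-04, and adjusted p = 0.390 with an estimated correlation), but part of that rise is shared with the region. From 47 Mb on chromosome 19, 96 of 104 rose, and their median difference from the 20 nearest other genes was 0.01 (95% interval -0.06 to 0.14), in line with a shift of the whole region. Over all 505 the median went from 0.27 to a difference of 0.11 from those neighbours (95% interval 0.04 to 0.20), which argues against a regional shift as the whole cause. The camera call nevertheless ended with neighbourhood medians taken out, and why was not tested. A few regions may carry the list, since without chromosome 19 the median was 0.08 (95% interval -0.05 to 0.18); regions chosen after their values were seen include chromosome 7 from 50 to 70 Mb, where 16 genes had a median of 2.44 with -0.12 around them, and chromosome 19 from 36 to 38 Mb, where 27 genes had 0.10 with -0.81 around them.

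Silent genes of the control cells were detected in the SETDB1 knockout, whereas the reverse was rare: 80 genes had at most 3 counts in control and at least 1 CPM in knockout, and 1 gene, PLXNA2, had the reverse, which argues against libraries from another cell line, since these would differ both ways. RNA of endothelial or fibroblast cells is argued against by a ratio of 0.76 in their summed markers, knockout over control, with COL1A1 at 0.756 against 1.14 CPM and VWF at 0.0619 against 0.327 CPM, and a gain of DNA copies by neighbours with a median of at least 0.3 around only 7 of the 80. White blood cells are argued against by their abundant transcripts: the 6 with a value, of 28 listed, rose together by 0.402 CPM, 0.0784% of the 513.3 CPM of the 80 genes, with LYZ at 0.252 against 0.248 CPM, LAPTM5 at 0.307 against 0.365 CPM, and HLA-DRA and CD74 higher but at only 0.356 and 0.155 CPM. An earlier test on blood cell markers had not decided, since the ratio of their 3 tested markers was 2.21, and red blood cells stay open because haemoglobin genes were not analysed here. Loss of SETDB1-dependent silencing is consistent with this one-sidedness as a hypothesis, but a difference between the cell populations that was present before the edit remains open.

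Chance in the grouping of the libraries was examined with all 10 splits of the 6 libraries into 3 and 3, of which 1, the real one, gave as many genes. The real split gave 5635 higher and 5584 lower genes and the highest of the other splits gave 0. With 10 splits the share cannot fall below 0.1, so it cannot reach 0.05. Every other split mixes libraries of both groups, so a strong group difference becomes spread within its groups and leaves few calls. The 0 therefore adds no separate support.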
